A study of Mus musculus with 14 samples.

How the data were processed

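PRDM16 ChIP-seq and input libraries of mouse ventricles at E13.5 were described by the labels of 14 samples in 8 groups. Tissue was crosslinked with EGS and formaldehyde and chromatin was selected by size, per the labels. The processed files are a peak list for WT whole-heart ventricles, a peak list for Prdm16cKO ventricles and a table of LV against RV. BWA 0.7.12-r1039, MACS2 2.1.1.20160309, HOMER and DESeq2 and the builds GRCm38 and mm10 are named per the submitters' processing notes, with no role or order. How replicates were pooled for the peak lists, which filters were used and which test gave the p-values of the table are not stated.

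The deposited peak lists carry a score that equals 10 times the -log10 q rounded down, a signal column that is the ratio of ChIP to background (fold enrichment) as the authors' peak caller gave it, the -log10 p-value and the -log10 q of each peak, and a summit offset. Per the file headers, the LV and RV columns of the deposited table hold the signal of each ventricle, log2mean and log2FC are on a log2 scale, and pvalue and qvalue hold a p-value and an adjusted p-value. The authors' log2FC equalled log2 of RV over LV to within 1.2e-14, so that positive values are higher in RV, and the 17587 regions of the table were the 17587 WT peaks. Column names of region start and end in that table refer to transcription start sites, but their values were the starts and ends of the peaks. Each LV and RV value equalled 0.5 plus the mean of whole reads times a factor per library. This gave exactly 1 solution in whole reads for 100% of regions (largest residual 5.9e-12, tolerance 1e-07), with 0.744 and 1.47 normalized reads per read in LV libraries A and B and 0.866 and 0.965 in RV libraries A and B. Tested on simulated data with similar factors, the procedure returned the reads put in at 100% of 17587 peaks. The simulated data were given peaks that set the offset and the step of each library, which the procedure needs. Which of the libraries A and B is replicate 1 or 2 of the labels is unknown. Reads of the inputs and of the whole-heart libraries are not in the files and were not used here.

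Peaks were compared with bedtools 2.31.1 (overlap of at least 1 bp). Chance overlap came from 10000 placements of the knockout peaks within the span of WT peaks on the same chromosome. Peaks were assigned by summit to the nearest protein-coding gene of a RefSeq table for GRCm38. The plan named the nearest transcription start site, but the table gives no strand, so that distance to the gene body was used, and for location distance to either end of the gene. Of 21887 genes, 7128 (32.6%) were nearest to at least 1 WT peak. The 23 lists hold 434 genes, of which 433 were found by symbol and 1 by a synonym. They were fixed before the data were examined, as were all tests and alternatives except those named as added or as not planned. Each list was compared, two-sided, with 10000 random lists of as many genes, matched on deciles of the length of sequence nearest to each gene, with Benjamini-Hochberg adjustment over lists. Random positions were drawn 100 times.

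For LV against RV the threshold was an adjusted p of 0.05 in the authors' deposited table. Median log2 RV over LV of each list with at least 3 regions was compared with 10000 random draws of as many regions, and, added after the data were seen, of as many genes. Also added was limma 3.58.1 with R 4.3.3 on log2 of normalized reads plus a pseudocount of 1, with a mean-variance trend and no minimum of reads, followed by camera (preset correlation 0.01, and estimated) and fry. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. limma was tested on simulated data in 20 runs of 17587 regions with 200 changed regions each: at regions with a mean of at least 8 reads it called 6.87% of 2-fold, 63.9% of 4-fold and 97.9% of 8-fold differences, with 26 false calls in all runs. In 20 simulated lists of 20 genes the list tests called 100% of planted differences, which for LV against RV were a log2 shift of -0.5, larger than the median of every list in the deposited table. In 80 random lists the adjusted test against random regions called 2.5%, and an unadjusted p under 0.05 came in 1.25% for genes with a peak, 5.00% for random regions and 3.75% for random genes.

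Genes were named by a rule fixed in advance: Prdm16, the 10 WT peaks and 5 knockout peaks of highest fold enrichment, the strongest peaks of up to 6 genes in each of 6 lists (compact myocardium, trabecular myocardium, left ventricle, right ventricle and second heart field, cardiac transcription factors, sarcomere) and of up to 3 genes in the others, and for LV against RV, since fewer than 5 regions passed, the 5 regions of smallest p on each side. Some genes that the rule names are not reported here. Motif searches were not analysed here, because no genome sequence of the build was at hand, nor were strand-dependent location classes, because the gene table gives no strand. Wilson intervals are 95% and cover counting error only. Alternatives tried were stricter peaks, other overlap rules, other gene assignments, unmatched lists, other thresholds, pseudocounts and scaling, a minimum of reads, replicate as a block, and each LV or RV library left out in turn, where the lone library of a ventricle was assumed to vary like the pair of the other.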

Results

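Binding of PRDM16 to DNA was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse ventricles at E13.5 (embryonic day). PRDM16 is a zinc-finger transcription factor that recruits chromatin regulators. The series holds 14 samples, of which 7 are PRDM16 ChIP libraries and 7 are input libraries of chromatin without antibody. Hearts with the atria removed gave 2 wild-type (WT) PRDM16 libraries and 1 library of the conditional knockout (Prdm16cKO), with 2 WT inputs and 1 knockout input. Each of these samples pooled 3 hearts of a single genotype. The left ventricle (LV) and the right ventricle (RV) of WT embryos gave 2 PRDM16 libraries and 2 inputs each, and every sample pooled 10 to 12 ventricles. Per the labels, replicates were pools of separate tissue. The files used here hold a WT peak list, a knockout peak list and a table of LV and RV values at the WT peaks, with total reads of no library. Reads within the 17587 WT peaks came to 330443 and 184244 in the LV libraries called A and B here, and to 281797 and 267808 in the RV libraries A and B. The median peak held 10 and 6 reads in LV and 9 and 8 reads in RV, which limits the differences that can be seen at a single peak. These letters carry no replicate number, and depth of the whole-heart libraries is not given in the sources used here.

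The first comparison, WT against knockout ventricles, served as the specificity control of the antibody. PRDM16 peaks numbered 17587 in WT and 330 in the knockout, a ratio of 53.3, and covered 6330 kb against 72.8 kb. The ratio was 37.3 at a -log10 q of at least 5 (11965 and 321 peaks) and 17.6 at a fold enrichment of at least 5 (4589 and 260). The peaks with the highest authors' fold enrichment lay in or near Arid1b (32.9), a chromatin remodelling subunit, Alk (32.4), a receptor tyrosine kinase, Ndufs6 (28.7), part of mitochondrial complex I, and Rbm39 (26.1), a splicing factor. They were followed by Josd2 (26.1), Prdm16 itself (25.7), Zfp36l1 (25.7), which promotes mRNA decay, Ryr2 (25.2), the calcium release channel of heart muscle, Ccny (23.6) and Myh7 (23.5), a myosin heavy chain. Of these 10 peaks the one assigned to Arid1b, on chromosome 17 at 4626084 to 4626707 and 367880 bp from the gene, overlapped a knockout peak, and the other 9 did not. Prdm16 was the nearest gene of 18 WT peaks, all inside the gene and none overlapping a knockout peak, with the strongest on chromosome 4 at 154392913 to 154394483. The peak of Ryr2 lay on chromosome 13 at 12132854 to 12134226, 26743 bp outside the gene, and that of Myh7 on chromosome 14 at 54996662 to 54997496, 2340 bp outside.

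Among the WT peaks, 197 (1.12%, 95% Wilson interval 0.975 to 1.29%) overlapped a knockout peak by at least 1 bp. These 197 had a median fold enrichment of 1.82, against 4.01 in the other 17390, and 39 of them lay at the start of chromosome 9 between 3000559 and 3037906. Of the 100 strongest WT peaks, 7 (7.0%, 3.43 to 13.7%) overlapped a knockout peak, against 13 of the next 900 (1.44%, 0.846 to 2.46%). At these 7 peaks, which include those of Arid1b, Dpp9, Gm8882 and Olfr854, the knockout fold enrichment was 0.67 to 1.82 times that of WT, with a median of 1.36. In the other direction, 215 of 330 knockout peaks (65.2%, 59.9 to 70.1%) overlapped a WT peak. Random placement of the knockout peaks on their chromosomes gave 1.31 overlaps on average and at most 7 (permutation p = 0.0001, one-sided, the smallest that 10000 placements can give). The 5 strongest knockout peaks had as nearest genes Gm8882 (fold 35.1, 99638 bp away), Arid1b (32.1, 367959 bp), Sulf1 (29.1, 47373 bp), a heparan sulfate sulfatase, Dpp9 (28.0, inside the gene), a dipeptidyl peptidase, and Olfr854 (26.7, 8107 bp), an olfactory receptor. All 5 overlapped a WT peak. With 1 knockout library and no values per library in either list, the difference in peak number was not tested, and the intervals cover counting error alone. The depths behind both lists are unknown, so that the ratio of peak numbers is not a ratio of binding.

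PRDM16 peaks lay at gene ends and inside genes more often than random positions did. Of the 17587 WT peak summits, 2884 (16.4%, 95% Wilson interval 15.9 to 17.0%) were within 1000 bp of an end of a protein-coding gene, against 3.11% of random positions, a ratio of 5.27. A further 8527 (48.5%) lay deeper inside a gene, against 39.3% of random positions. Outside genes peaks were fewer than at random, with 3436 (19.5%) within 50000 bp of a gene against 22.9%, and 2740 (15.6%) further away against 34.7%. The highest share of random positions within 1000 bp of a gene end in 100 draws was 3.41%. Peaks within 1000 bp of a gene end had a lower median fold enrichment (3.58) than those more than 50000 bp away (4.17). Either end of a gene counts here, because the gene table used gives no strand.

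The next question was which groups of heart genes carried PRDM16 peaks. Of 23 fixed lists, 11 did so more often than genes with as much surrounding sequence. The random lists were not matched on gene activity or open chromatin in the heart. Whether PRDM16 prefers these groups over other active genes was therefore not tested. A WT peak was assigned to 31 of 32 sarcomere genes, where 10.4 were expected (ratio 2.99), with the strongest at Myh7 (23.5), Ankrd1 (21.7), a titin-associated protein, and Myl2 (21.0), the ventricular myosin light chain. All 19 genes of noncompaction cardiomyopathy had a peak (8.72 expected), as did 23 of 24 cardiac transcription factor genes (13.3 expected), 18 of 19 genes of the trabecular myocardium (10.1 expected) and 23 of 25 genes of TGF-beta and BMP signalling (12.5 expected). Each of these 5 lists had a permutation p of 0.0002, the smallest that 10000 random lists can give, and an adjusted p of 0.00092 over 23 lists.

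Cardiac transcription factor genes had 204 peaks, among them those at Tbx20 (14.6), a T-box factor, Myocd (14.5), a coactivator of muscle genes, with 15 peaks, Tead1 (12.4), the DNA-binding partner of YAP, with 14, and Gata5 (10.8). Trabecular genes, active in the inner muscle layer, included Irx2 (15.2) and Irx3 (11.8), homeobox factors, Gja5 (13.7), a gap junction protein, Nppb (12.0), a natriuretic peptide, and Bmp10 (10.7), a growth factor of trabecular muscle. In the compact myocardium list, the outer muscle layer, 11 of 12 genes had a peak, a ratio of 1.47 to random lists that missed the threshold (adjusted p = 0.094). It passed with any gene within 50000 bp (0.028), genes within 10000 bp (0.011) and peaks of -log10 q of at least 5 (0.031). Against unmatched lists it also passed (0.00092), but so did 18 lists in all, neuronal genes among them (0.00092). With WT peaks that overlap no knockout peak the compact myocardium list did not pass (0.09). Its members included Hey2 (12.2), a repressor of the compact layer, on chromosome 10 at 31052816 to 31053853 and 210670 bp from the gene, Fstl4 (10.4) and Mycn (8.31), a driver of proliferation, whose peak was high in LV library A (812 reads, against 25, 34 and 79 in the other libraries), while Ccnd1 had none. Counted as peaks rather than genes, a count added after the data were seen, that list held 84 against 25.9 expected (ratio 3.25, adjusted p = 0.0028). The left ventricle list had 6 of 7 genes with a peak (2.71 expected, adjusted p = 0.033, but 0.10 with genes within 10000 bp only), among them Nppa (10.1), a natriuretic peptide, and Tbx5 (9.04) and Hand1 (7.82), transcription factors of the left ventricle. The right ventricle and second heart field list had 10 of 13 (ratio 1.53, adjusted p = 0.094), with Mef2c (7.66) and Hand2 (5.30), which had 12 peaks. None of the list peaks named here overlapped a knockout peak.

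Other lists past the threshold were calcium handling and ion channels with 18 of 19 genes (adjusted p = 0.0015; Atp2a2, the calcium pump, 22.8; Cacna1c, a calcium channel, 21.7), and atrial genes with 11 of 12 (0.0026). Glycolysis and hypoxia genes had 13 of 20 (0.0098; Hk1, hexokinase, 11.4), conduction system genes 13 of 15 (0.010; Cacna1g, a calcium channel, 13.2), and genes of fatty acid oxidation and brown fat 13 of 21 (0.010; Ppargc1a, a coactivator of mitochondrial genes, 9.11, with 18 peaks). Lists that did not pass were Notch signalling with 12 of 18 genes (adjusted p = 0.11), Wnt signalling with 17 of 24 (0.17), the cell cycle with 11 of 20 (0.18), endothelium and endocardium with 12 of 20 (0.22), smooth muscle with 7 of 12 (0.22) and fibroblasts and valve mesenchyme with 14 of 20 (0.36). Neuronal genes, whose long surroundings collect peaks by chance, had 22 of 34 (ratio 1.03, adjusted p = 1.0), and epicardial genes 6 of 14 (1.01; 1.0). Erythroid and immune genes had 3 of 16 (ratio 0.687, adjusted p = 0.66) and hepatocyte genes 1 of 18, which was Apob (0.198; 0.063). In all, 11 lists lay above random lists and 0 below at adjusted p of 0.05 in 10000 random lists matched on the length of sequence nearest to each gene, two-sided; 12 lists had an unadjusted p under 0.05, with hepatocyte genes as the addition (0.033). Counted as any gene within 50000 bp of a summit, 7 lists lay above random lists: the trabecular (adjusted p = 0.19), left ventricle (0.28), glycolysis (0.37), fatty acid oxidation (0.19) and atrial (0.20) lists no longer passed, and compact myocardium did. With genes within 10000 bp only, 10 lists did: the left ventricle (0.10) and atrial (0.088) lists no longer passed, and compact myocardium did. Counted as peaks, the trabecular (0.071), left ventricle (0.071), conduction (0.051), fatty acid oxidation (0.071) and atrial (0.17) lists did not pass, while compact myocardium and Notch signalling (0.0085) did.

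**Figure D1:**
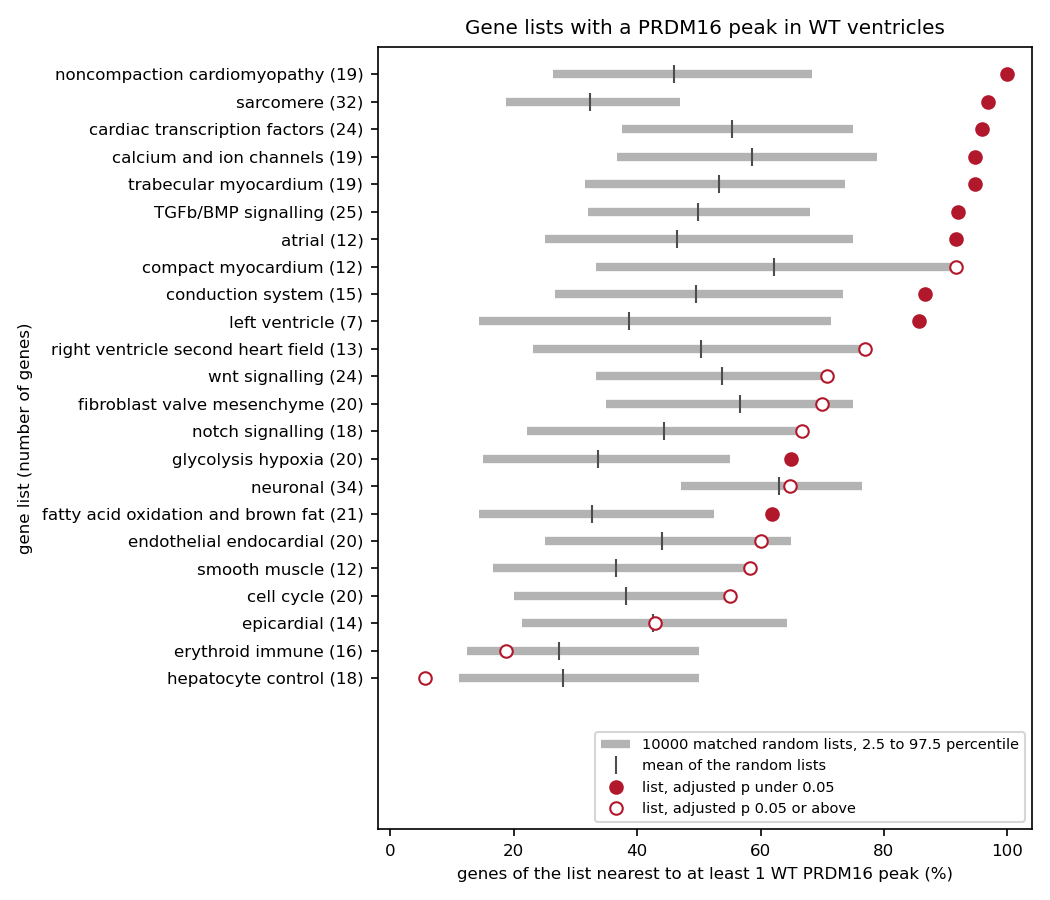
Percent of the genes of each fixed list that are nearest to at least 1 WT PRDM16 peak (horizontal axis, points), with the mean and the central 95% range of 10000 matched random lists (tick and grey bar); the number of genes stands in brackets. Filled points mark the 11 lists past adjusted p of 0.05, and sarcomere genes stood at 96.9% against 32.4% in random lists.

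LV against RV asked whether PRDM16 binds differently in the ventricles at the same peaks. Regions at Tbx5 and Hand1, transcription factors of the left ventricle, had the higher values in LV, and a region in Opcml, a neural cell adhesion molecule, had the higher value in RV. In the authors' deposited table the Tbx5 region, on chromosome 5 at 119796420 to 119796866 and 141 bp from an end of the gene, had 31.6 normalized reads in LV and 6.52 in RV (log2 RV over LV -2.27). The region nearest to Hand1, on chromosome 11 at 57847449 to 57848017 and 15574 bp from the gene, had 32.2 and 6.96 (-2.21). Values of the strongest Tbx5 peak, on chromosome 5 at 119857055 to 119857620, differed by 0.12. Neither these regions nor any other passed: in the authors' deposited table, whose test is not named, 0 of 17587 regions had an adjusted p under 0.05 or 0.1. The smallest adjusted p was 0.444, in regions inside Ptprn2, a protein of secretory granules (47.4 in LV and 8.31 in RV, log2 -2.51), and Tenm4, a cell surface protein (136 and 45.6, log2 -1.58). At an unadjusted p under 0.05 there were 85 regions, 60 higher in LV and 25 higher in RV, where uniform p-values would give 879. A lack of differences alone would give uniform p-values, so that 85 regions, with a median p of 0.666 over all regions, point to a strict test. The 0 calls thus do not tell whether binding differed. Over all regions the median log2 difference was -0.0028 (SD 0.626 across regions), and 1870 regions differed by a log2 of at least 1.

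Other regions with the smallest p in the authors' deposited table were, on the LV side, one with Cxcl12, a chemokine, as its nearest gene. It lay on chromosome 6 at 117275855 to 117276168, 94572 bp from the gene (23.5 in LV and 0.933 in RV). On the RV side they were Opcml on chromosome 9 at 27935252 to 27935723 (7.49 in LV and 30.1 in RV, log2 2.01) and a region inside BC052040 (1.56). The others there had as nearest genes Rchy1 (log2 2.29, 141478 bp away), Parp11 (1.06, 135066 bp) and Tbx19 (1.32, 98071 bp). The strongest peak of Prdm16 had 199 in LV and 198 in RV, that of Myh7 had 92.5 and 108, and that of Hey2 had 60.5 and 51.9, with log2 differences of -0.0022, 0.22 and -0.22 (0.37 for Hey2 without LV library A).

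Whole reads per library, worked out from the LV and RV columns after the data were seen, allowed a limma test (n = 2 pools per ventricle). It called 5 of 17587 regions at adjusted p under 0.05, all higher in LV: Ptprn2 (log2 -2.45, SE 0.350, adjusted p = 0.00126), Cxcl12 (-3.95, SE 0.657, 0.0101), Tbx5 (-2.21, SE 0.402, 0.0186), Hand1 (-2.14, SE 0.388, 0.0186) and St18, a zinc-finger factor (-2.03, SE 0.369, 0.0186), which lies outside the naming rule and was chosen after its values were seen. Cxcl12 had 1 and 0 reads in RV, so that its log2 hung on the pseudocount (-6.02 at 0.1, -2.24 at 5). Its limma adjusted p was 0.28 at a pseudocount of 0.1 and 0.553 at a mean of at least 8 reads. At a pseudocount of 0.1 Tbx5, Hand1 and St18 did not pass either (0.125 each), and Ptprn2 alone did. At a pseudocount of 5 all 5 passed. Reads in LV libraries A and B and RV libraries A and B were 50, 17, 5 and 8 at Tbx5, 36, 25, 6 and 8 at Hand1, and 5, 7, 36 and 29 at Opcml, whose limma adjusted p was 0.0654. limma gave 1111 regions at an unadjusted p under 0.05, where chance gives 879, with 551 higher in LV and 560 higher in RV. Adjustment over a list alone was not planned and does not correct for the number of lists tried. Adjusted in this way, 2 regions of the left ventricle list, those at Tbx5 and Hand1, passed in the authors' deposited table (adjusted p = 0.011 for both) and with limma (5.6e-05 for both). Adjusted over the list alone with limma, 2 regions of cardiac transcription factors (the same Tbx5 and Hand1 regions, 0.00054), 1 of the trabecular list (Irx2, log2 -1.33, SE 0.334, 0.027) and 1 of the neuronal list (Opcml, 0.0018) also passed, and 0 of these did with the p of the authors' deposited table (0.11, 0.98 and 0.21). Without RV library A or without RV library B limma called 0 regions, although the log2 of the 5 stayed at -4.40 to -1.85, and it called 90 without LV library A (3 of the 5 among them; 17 higher in LV and 73 higher in RV) and 22 without LV library B (4 of the 5; 14 and 8). Splits that mix the ventricles, with LV library A and RV library A or B against the other 2 libraries, gave 0 calls (988 regions at an unadjusted p under 0.05) and 3 calls (543). In simulated reads at this depth, at regions with a mean of at least 8 reads, limma called 6.87% of regions with a 2-fold, 63.9% with a 4-fold and 97.9% with an 8-fold difference, so that a 2-fold difference at a single region was mostly not detectable. Regions below that mean were not among the changed ones.

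**Figure D2:**
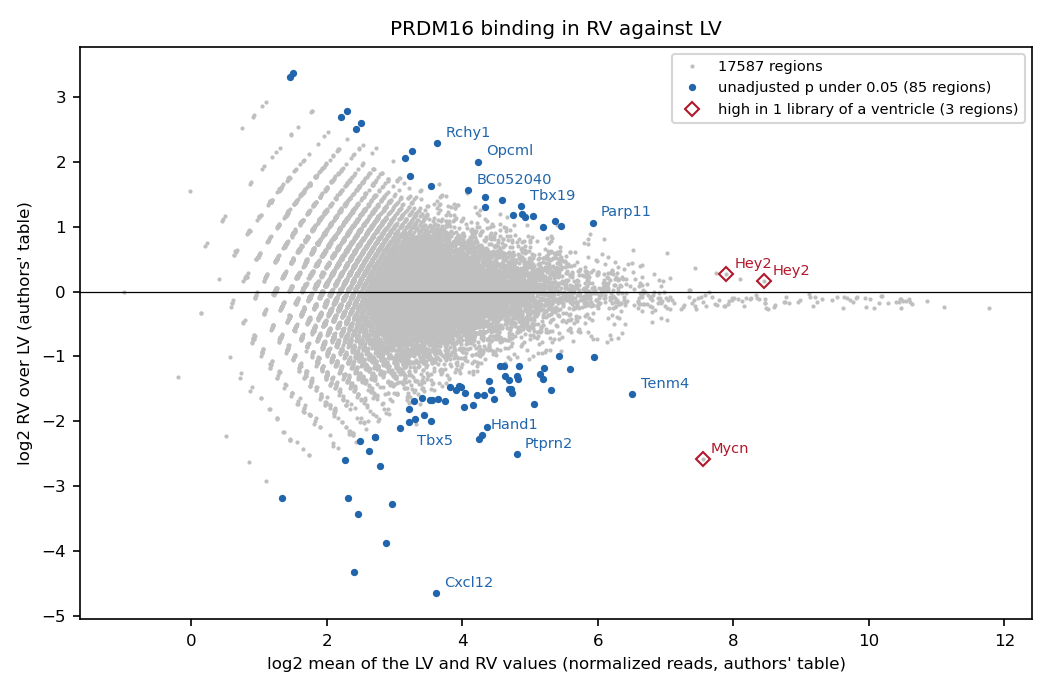
Log2 of RV over LV (vertical axis) against the log2 mean of the LV and RV values (normalized reads, horizontal axis) for the 17587 regions of the authors' deposited table. Blue points are the 85 regions with an unadjusted p under 0.05 (named genes labelled), and red diamonds are 3 regions near Hey2 and Mycn that were high in 1 library of a ventricle.

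**Figure D3:**
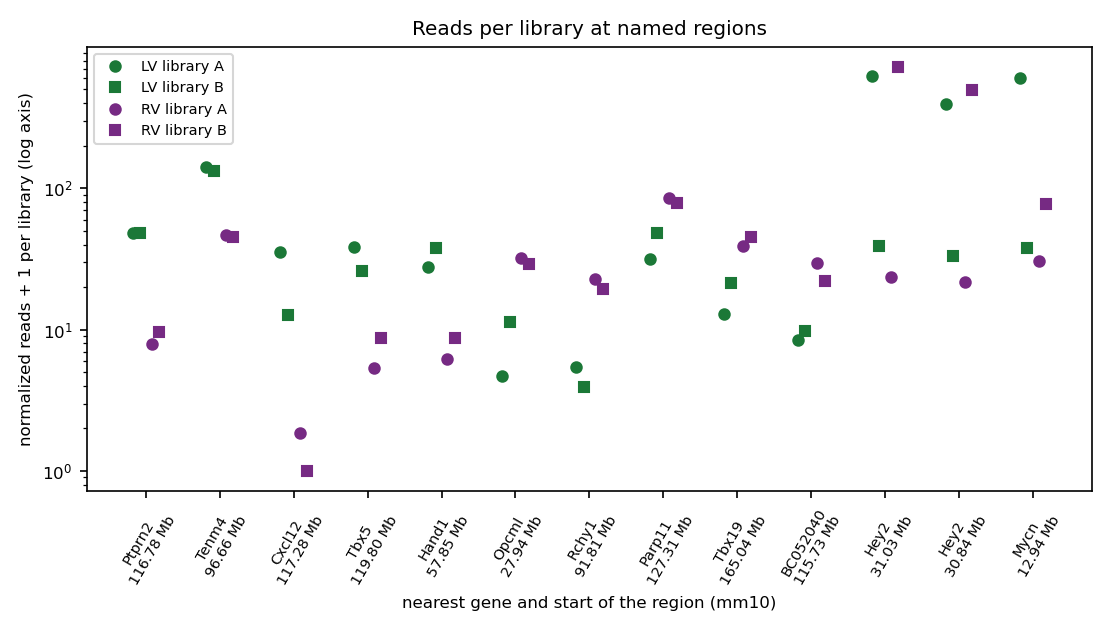
Normalized reads plus 1 in each library (logarithmic vertical axis) at named regions (horizontal axis, nearest gene and start), with LV libraries A and B in green and RV libraries A and B in purple. The Tbx5 and Hand1 regions were higher in both LV libraries, while the Hey2 regions were high in LV library A and RV library B.

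Taken by gene list, LV values were higher than RV values at most regions of the trabecular and left ventricle lists, but neither call held under all settings. Of 69 regions of trabecular genes, 53 were higher in LV (median log2 RV over LV -0.24), among them the strongest peaks of Irx3 (-0.50), Nppb (-0.34) and Gja5 (-0.20). Of 21 regions of the left ventricle list, 16 were higher in LV (median -0.42), with Hand1 at -2.21, Nppa at -0.42 and the strongest Tbx5 peak at 0.12. Neuronal genes had 45 of 77 regions higher in RV (median 0.28), with Opcml at 2.01 and Ntm, its neighbour in the same adhesion family, at 0.58. Atrial genes had 20 of 35 higher in LV (median -0.42, but 0.04 without LV library A, 0.15 at a mean of at least 8 reads and -0.03 with any gene within 50000 bp), although their strongest peaks, at Pam (0.39), Tbx18 (0.45) and Myl4 (0.08), had the higher values in RV. Several of these single peaks changed sign without 1 library, as Nppa did without LV library A (0.05), Gja5 without RV library B (0.14), Myl4 without LV library B (-0.12) and the Tbx5 peak without LV library A (-0.09). Against random draws of as many regions, these 4 of 22 lists passed: trabecular and left ventricle genes at adjusted permutation p = 0.029, neuronal and atrial genes at 0.0055. By the share of regions higher in LV the trabecular list alone passed (0.0022), and the left ventricle (0.26), neuronal (0.55) and atrial (0.72) lists did not. With any gene within 50000 bp the trabecular (adjusted permutation p = 0.067) and left ventricle (0.081) lists did not pass, and the neuronal list alone did (0.016). Beyond 1000 bp of a gene end the trabecular (0.088) and left ventricle (0.70, median -0.26) lists did not pass either. There the neuronal and atrial lists did (0.0055 for both). At a mean of at least 8 reads none passed (trabecular and neuronal 0.078, left ventricle 0.54, atrial 0.58). Against random draws of as many genes, added since regions of a gene are not independent, 0 lists passed (0.18 for trabecular and left ventricle genes, 0.052 for neuronal and atrial genes), and 4 had an unadjusted p under 0.05. With limma's camera on reads per library the trabecular (adjusted p = 0.024) and left ventricle (0.0020) lists passed at a preset correlation of 0.01, with adjusted p = 0.80 with an estimated correlation for both, and fry called 0 lists (0.17 and 0.51), with 1 list at an unadjusted p under 0.05. Camera did not pass the neuronal and atrial lists (0.52 for both). The trabecular and left ventricle lists share Nppa, Nppb and Gja5. The atrial list also holds Nppa, whose region is the middle value there. These lists are thus not independent.

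No other list differed between the ventricles against random regions. Compact myocardium had a median of -0.08 (adjusted p = 0.74), notch signalling 0.11 (0.63), epicardium 0.23 (0.63), and fibroblasts and valve mesenchyme 0.14 (0.63). The remaining lists had medians from -0.09 to 0.11 with adjusted p from 0.85 to 0.95. Hepatocyte genes, with 1 region, were not tested. Median and mean differed in sign for cardiac transcription factors (0.01 and -0.02), Wnt signalling (0.02 and -0.04), glycolysis (-0.09 and 0.02), fatty acid oxidation (-0.03 and 0.13), epicardium (0.23 and -0.17) and erythroid genes (0.01 and -0.10). Camera gave LV as the direction for all of these except fatty acid oxidation, for which it gave RV. Without LV library A or without RV library A, 0 of the 4 lists kept their call, without LV library B the trabecular list did (0.033), and without RV library B the left ventricle list did (0.0066). The left ventricle median was then -0.21 (without LV A), -0.28 (LV B), -0.19 (RV A) and -0.70 (RV B). The neuronal median was 0.30, 0.19, 0.18 and 0.10. The trabecular median stayed between -0.29 and -0.27.

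**Figure D4:**
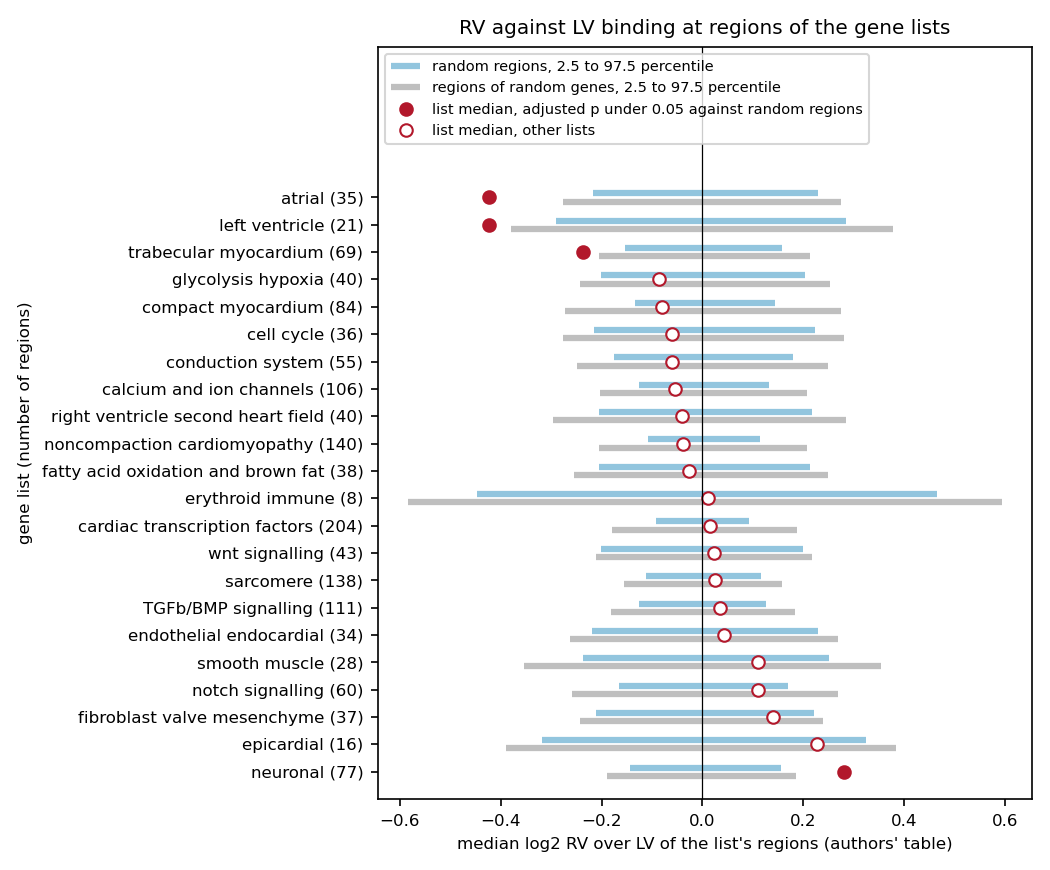
Median log2 of RV over LV of the regions of each fixed list (points; number of regions in brackets) with the central 95% range of random draws of as many regions (blue bars) or genes (grey bars). Filled points mark lists past adjusted p of 0.05 against random regions: the trabecular (-0.24), left ventricle (-0.42) and atrial (-0.42, but 0.04 without LV library A) lists lay on the LV side and the neuronal list (0.28) on the RV side.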

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

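Among the alternatives, limma on reads per library with its own alternatives (replicate as a block included), random genes in place of random regions, camera and fry, a mean of at least 8 reads in the list test, the removal of regions high in 1 library, and numbers of peaks were added after the data were seen. Adjustment of p-values over a single list was not planned either. The overlap of knockout with WT peaks stayed far above chance under all 3 other rules (31.8% to 56.1%). Requiring a fold enrichment of 5 left 4589 WT and 260 knockout peaks, a ratio of 17.6 in place of 53.3. Peaks within reach of a gene end were 22.3% at 2500 bp and 14.4% at a -log10 q of at least 5. The number of gene lists above random lists was 7 with any gene within 50000 bp and 18 without matching, and 1 list, hepatocyte genes, lay below in both and with genes within 10000 bp only. The single lists kept their call and direction in 105 comparisons, gained a call in 16, lost it in 12 and turned in 5, none of which had a call: the ratio was 0.958 for neuronal genes at a -log10 q of at least 5, 0.820 for epicardium within 10000 bp, and with numbers of peaks 0.928 for neuronal genes, 0.889 for epicardium and 0.985 for fibroblasts and valve mesenchyme. For LV against RV regions, 0 in the authors' deposited table became 5 with limma, 1 with a pseudocount of 0.1, 14 with 5, 5 with library totals as scaling, 8 at a mean of at least 8 reads, and 0 to 90 without 1 library, a lone library being assumed to vary like the others. The number of lists that differed between LV and RV, 4 as reported, was 1 with any gene within 50000 bp, 2 beyond 1000 bp of a gene end, 1 (trabecular) by the share of regions higher in LV, 0 against random genes, 0 at a mean of at least 8 reads, 2 with camera at a preset and 0 at an estimated correlation, 0 with fry, and 0 to 1 without 1 library. Any gene within 50000 bp left the neuronal list alone, and regions beyond 1000 bp of a gene end left the neuronal and atrial lists. The trabecular and left ventricle lists lost their calls in both. The fry test asks whether a list moves one way and does not compare it with other lists. Single lists kept call and direction in 153 comparisons, lost the call in 28 and turned, against the median of all regions, in 39, of which atrial genes alone had a call. The turned medians were 0.15 (atrial), -0.0022 (compact myocardium), 0.076 (right ventricle and second heart field) and -0.0058 (noncompaction) at a mean of at least 8 reads. With any gene within 50000 bp they were -0.0057 (TGF-beta and BMP), 0.074 (cell cycle), 0.031 (fatty acid oxidation), -0.094 (endothelium), -0.023 (smooth muscle) and -0.0093 (erythroid). Beyond 1000 bp of a gene end they were 0.048 (fatty acid oxidation), -0.22 (epicardium) and -0.018 (erythroid), and 50% of the regions of fatty acid oxidation were higher in LV. Without 1 library the medians ranged from -0.19 to 0.038 (atrial), -0.15 to 0.039 (compact), -0.14 to 0.15 (noncompaction), -0.081 to -0.0040 (Wnt), -0.11 to 0.033 (glycolysis), -0.021 to 0.16 (fatty acid oxidation), -0.18 to 0.12 (epicardium), -0.054 to 0.072 (smooth muscle), -0.27 to 0.041 (erythroid), -0.097 to 0.058 (right ventricle and second heart field), -0.085 to 0.12 (cardiac transcription factors) and -0.17 to 0.17 (sarcomere). The Mycn region ranged from -3.50 to 0.52 without 1 library, and the 5 regions of smallest p on each side kept their direction in all such comparisons, which a choice by small p nearly fixes. Of 70 strongest peaks of list genes, 40 changed sign without 1 library, 0 of them with an unadjusted p under 0.05 in the authors' deposited table. Except where fewer libraries or regions show it, the cause was not tested. Which recovered libraries share a replicate number is unknown, and their deviations did not go together (correlation of A minus B in LV and RV 0.0732 across 8569 regions); with a replicate block limma called 50 regions if LV library A and RV library A share a number, and 12 if LV library A and RV library B do, with all 5 regions among them in both. Not run, although planned, were DESeq2 and TMM scaling and the filter on low counts that goes with them, and the motif searches, and a restriction to regions that overlap a WT peak moves nothing, since all regions are WT peaks. Depth limits the single-region test: 2-fold differences were called in 6.87% of simulated cases at regions with a mean of at least 8 reads.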

Other observations

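Leaving out 1 library was planned, and the other tests in this part were chosen after the results were seen.

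Genes not yet named collected many PRDM16 peaks in WT ventricles. Zmiz1, a transcriptional coregulator, was the nearest gene of 30 peaks, Zfp608, a zinc-finger protein, of 29, and Tns1, a protein of focal adhesions, of 26. Rbm20, the splicing regulator of titin and a member of the noncompaction list, had 28 peaks, or 13.0 per 100 kb of the sequence nearest to it, against 5.23 for Prdm16, 4.27 for Zmiz1, 2.29 for Zfp608 and 1.23 for Auts2. Gse1 and Auts2 had 24 each, Msi2, an RNA-binding protein, 23, and Bach2 and Nfib, transcription factors, 22 each. Of the peaks of Rbm20, Zmiz1, Tns1, Gse1, Msi2, Bach2 and Nfib, 0 overlapped a knockout peak, and 1 each of those of Zfp608 and Auts2 did. These genes were chosen after their peak numbers were seen, and the numbers were not tested against chance.

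Alkbh8 headed the count with 40 peaks, and all 40 overlapped knockout peaks. It was the nearest gene of regions at the start of chromosome 9, such as 3001632 to 3002837 (fold enrichment 1.82). That cluster held 39 WT peaks between 3000559 and 3037906, all of which overlapped knockout peaks. The count thus goes largely with the cluster and does not mark Alkbh8 as a bound gene. The region with the most reads, on chromosome 1 at 24612889 to 24616187 with Col19a1 as its nearest gene, held 3421 and 3427 reads in LV libraries A and B and 3451 and 3488 in RV libraries A and B at a length of 3299 bp. Peaks that overlapped a knockout peak took from 19.0% to 30.6% of the reads in peaks of the 4 LV and RV libraries. Across 8569 regions with a mean of at least 8 reads, log2 values of the LV libraries differed from each other with an SD of 0.676 and those of the RV libraries with an SD of 0.599, while pairs across the ventricles gave 0.609 to 0.721.

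WT peaks that overlap knockout peaks came with a weak enrichment in WT and many reads. The knockout peaks themselves were not weak, with a median fold enrichment of 5.99 over all 330, overlapping or not. The 197 WT peaks concerned held a median of 1570 LV and RV reads per kb against 109 in the other WT peaks, a ratio of 14.4. Their fold enrichment was lower all the same. Sequence that gives many reads in any library would do this, so that repeats are a candidate explanation of these WT values. Whether repeats explain the enrichment in the knockout was not tested. Outside the start of chromosome 9 and chromosome Y, 154 of the 197 WT peaks still held 1030 reads per kb. PRDM16 left in the knockout tissue as the whole cause would make the overlapping WT peaks the stronger ones. Their median fold enrichment was 0.454 times that of other WT peaks. That ratio does not decide the question, since fold enrichment may not follow binding there. Of the 197 overlapping peaks, 138 had a fold under 2, and 10 shared a value of 1.82 that 0 of the other WT peaks had. At the strongest 100 WT peaks, of which 7.0% (3.43 to 13.7%) overlapped a knockout peak, more than in each weaker class (0.6 to 1.44%), remaining PRDM16 cannot be told apart from other sources: that share goes with it, the knockout fold of 1.36 times that of WT at the median of these 7 peaks does not, and depths and input reads are not in the files.

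The regions near Tbx5 and Hand1 may be bound more in LV, as a hypothesis that these data do not settle. A single library as the cause cannot be told apart from a ventricle difference: the log2 RV over LV of both regions stayed between -2.71 and -1.94 when any 1 of the 4 libraries was left out, but both were chosen for a small p, and 84 of the 85 regions of unadjusted p under 0.05 had LV libraries apart from RV libraries, so that the choice fixed this outcome, and limma called neither region without RV library A (adjusted p = 0.981) or RV library B (0.992), Tbx5 not without LV library A (0.0532) and Hand1 not without LV library B (0.0917). A shift shared by all regions is removed by the scaling. Stronger immunoprecipitation in LV that raises strong regions over weak ones is argued against as the cause of differences this large. Both regions lie in the strongest of 5 groups of regions by whole-heart enrichment. The median log2 RV over LV of that group was 0.012, which is 0.042 above that of the weakest group. A smaller effect of this kind is not excluded. Chance is not excluded: 2 regions of the left ventricle list stood among the 60 LV-higher regions of unadjusted p under 0.05, where 0.072 were expected, and Fisher's exact test gave p = 0.0023, one-sided, or 0.051 after adjustment over the lists. Whether LV and RV differ in open chromatin or in the share of cells that carry PRDM16 also stays open. The samples are PRDM16 ChIP and input libraries, which measure neither directly, and the inputs of LV and RV were not analysed here.

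At regions near Hey2 and in Mycn, genes of the compact layer, 1 library of a ventricle held far more reads than the other: on chromosome 10 at 31034760 to 31035467 LV libraries A and B had 840 and 26 and RV libraries A and B had 26 and 744, at 30841987 to 30842367 they had 533, 22, 24 and 515, and on chromosome 12 at 12941612 to 12942074 they had 812, 25, 34 and 79. With the labels as given, a difference between the ventricles is argued against at the Hey2 regions, whose log2 RV over LV was at most 0.27 against an excess of 1 library of at least 3.58. More DNA of the whole locus is argued against by neighbours within 500000 bp of the Hey2 regions, whose median log2 excess in the same libraries was 0.386 (highest 1.85) against 3.58 to 4.93 at the regions themselves. A swap of an LV with an RV label stays open: LV library A and RV library B against the other 2 libraries gave 543 regions at an unadjusted limma p under 0.05, where chance gives 879, and called these 3 regions alone (smallest adjusted p 3.22e-09), but the other mixed split gave 988 and the split by labels the most, 1111 with 5 calls, among them Tbx5 and Hand1 with more reads in both LV libraries, which goes with the labels but was found by that split itself; amplified DNA of these few regions also stays open, since read positions are not given. At the Mycn region a ventricle difference, the biological explanation the design gives, also stays open. Its log2 RV over LV of -2.59 in the authors' deposited table became 0.52 without LV library A, and 1 LV library then remains. The higher libraries there were the same as at the Hey2 regions, LV library A (log2 excess 4.01) and, by less, RV library B (1.34).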
